A study of Danio rerio with 10 samples.

How the data were processed

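RNA from sorted microglia and from the other cells of the same kind of brain was measured by sequencing in 3-month-old zebrafish that carried the transgenes Neuro:NTR-mCherry and mpeg1:GFP. The mpeg1 promoter is active in macrophages and microglia, and NTR (nitroreductase) turns the drug metronidazole (MTZ) into a toxic product in the cells that hold it, here neurons. Fish received MTZ for 24 or 48 h (activated microglia) or the solvent DMSO (control microglia), brains were dissociated with trypsin on ice, and GFP-positive cells were sorted after a Percoll gradient. GFP-negative cells served as other brain cells, and the labels do not give the treatment of their fish. The labels name 3 control microglia, 3 other brain cell, 2 activated 24 h and 2 activated 48 h samples, identified here by group and sample number. They do not say whether samples came from separate animals, so p-values measure only the spread between samples.

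The submitters' processing notes name TopHat2 2.0.5, SAMtools 0.1.18, edgeR with no version and genome build GRCz10, and state neither the counting tool, the annotation, the filter nor the scaling. The first deposited table holds a signal per gene and library for 21756 genes, a read coverage scaled by the authors. It is not plain CPM, because the column sums of the deposited table ran from 728524 to 1444667. Within each column, every value lay within 0.05 steps of a whole number of equal steps above 1 constant shared by all columns, so the constant stands for 0 reads, and totals of reads could be computed from the steps. These totals ran from 6185540 to 12815571 per library, and 1 read was worth between 0.072 and 0.1545 units of signal. The second deposited table holds the authors' log2 fold changes and the authors' FDR for 5 comparisons. Its column for pooled activated microglia equals the mean of the 24 h and 48 h columns, with a largest difference of 1.5e-08. It does not name the libraries behind each comparison. The reference at hand carries gene names of a later genome build, so no gene positions are given and no check by transcript length was made.

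The deposited column of control microglia sample 9 is identical to that of activated microglia 24 h sample 3 in all 21756 genes. No other pair of columns shared more than 1376 values. The plan made before the data were examined used all 3 control columns. After the identity was seen, control sample 9 was left out of every main fit and the column was used as 24 h sample 3, which leaves 2 control microglia libraries. This choice departs from the plan and decides the outcome for activated microglia. With the column used as a control, as deposited, the comparison of activated with control microglia called 0 genes higher and 0 lower, and with both identical columns left out it also called 0 and 0. The reason for the choice was a check against the authors' deposited fold changes in 7299 genes with a mean value of at least 20. The deposited 24 h minus 48 h folds lay a median of 0.027 (log2) from folds that used the column as 24 h and 0.112 from folds that left it out. The deposited 48 h minus control folds lay 0.146 away without the column among the controls and 0.212 away with it. The check shows that the authors' fit used the column as 24 h. For the control group, folds lay farther than 0.027 from the deposited ones with either set of controls. They lay farther with the column among the controls, also for control minus other brain cells (0.203 against 0.168), which argues against its use there. The full set of libraries behind the authors' control group thus remains unknown. The check also does not show which library the column was.

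Genes with a value of at least 1 in at least 2 libraries were kept (21714 genes). Values were transformed as log2(value + 1) and fitted with limma 3.58.1 (R 4.3.3, statmod 1.5.0; lmFit and eBayes with a mean-variance trend), with two-sided tests, Benjamini-Hochberg adjustment over all genes tested and calls at an adjusted p under 0.05. A set of 5 comparisons were made: control microglia against other brain cells, activated (24 h and 48 h pooled, as the series states) against control microglia, each time point against control microglia, and 48 h against 24 h. The last 3 shared a fit with 3 groups. Fold changes are the first group minus the second, on the log2(value + 1) scale, which shrinks the change of genes with low values, with their standard error (SE); group values are means with their standard deviation (SD). Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

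A set of 27 gene lists was fixed before the data were examined: microglia core, antigen presentation, complement, DNA replication, mitosis, inflammatory mediators, interferon response, chemokines and receptors, pattern recognition, lysosome, damage-associated microglia, cholesterol synthesis, glycolysis, mitochondrial respiration, cytosolic ribosome, unfolded protein response, immediate early and heat shock, p53 and apoptosis, oxidative stress (Nrf2), and markers of neurons, radial glia and astrocytes, oligodendrocytes, endothelial and mural cells, erythrocytes, neutrophils, lymphocytes, and other macrophages and dendritic cells. Each list was tested with limma camera at a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry, which tests whether the genes of a list move one way on balance and does not compare them with other genes. Adjustment was by Benjamini-Hochberg over the 27 lists. Members called were also counted after adjustment over the list alone.

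Genes are named by a rule fixed before the data were examined. It takes 15 set genes (mpeg1.1, apoeb, p2ry12, csf1ra, slc7a7, irf8, spi1b, il1b, tnfa, pcna, mki67, gfap, snap25a, elavl3 and mbpa). It adds the 10 highest and 10 lowest called fold changes of the first 2 comparisons (5 for 48 h against 24 h), among genes with a mean of at least 5 in the higher group, no overlap between groups and a symbol that is not a clone name. It also adds, for each list, the called members with the highest and lowest fold change and the 2 with the highest mean value. Genes named outside the rule are marked as chosen after their values were seen.

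Alternatives fixed beforehand were pseudocounts of 0.25 and 5, no filter, a filter at 5, median-of-ratios scaling, quantile normalization, limma without the trend, robust empirical Bayes, array quality weights, all 9 libraries in 1 fit, a block guessed from consecutive sample numbers, a threshold of 0.01, time points as separate groups, and leaving out each library in turn. Chosen after seeing the data were limma-voom on recovered reads and the other treatments of the identical columns. The edgeR and DESeq2 alternatives fixed beforehand were not run, and limma-voom on the recovered reads took their place. Also chosen after seeing the data were 6 further gene groups (proteasome subunits, chaperonin subunits, aminoacyl-tRNA synthetases, nucleoporins, coatomer and dendritic-like markers).

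On simulated counts with group sizes as in the fits, 13% of genes changed 2-fold, 85.7% of those changed 4-fold and 98.5% of those changed 8-fold were called for control microglia against other brain cells. For activated against control microglia the shares were 15.7%, 98.5% and 100%. For 48 h against 24 h they were 9.33%, 80.3% and 98.4%. The simulated spread came from the data through 1 dispersion for all genes, so these shares describe well-behaved genes. They likely overstate how many real changes of such size would be called. DNA replication genes had a median fold change of 2.1 (log2) in activated against control microglia, and most of them were still not called. A lack of calls is therefore no evidence of a lack of change.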

Results

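The transcriptome of sorted microglia, the resident macrophages of the brain, was measured in 3-month-old zebrafish with and without drug-driven loss of neurons, beside GFP-negative brain cells. Control microglia samples 1 and 5 held 6900171 and 6897191 reads. The 24 h samples 3 and 7 held 12815571 and 8600052 reads, and the 48 h samples 4 and 8 held 9325194 and 11497062. Other brain cell samples 2, 6 and 10 held 6185540, 8440776 and 10049275 reads. The column of control microglia sample 9 was identical to that of 24 h sample 3 and was left out, a choice made after seeing the data. So 9 of the 10 deposited libraries were used and control microglia had n = 2. Values are the authors' normalized signal, in which 3 reads corresponded to between 0.216 and 0.464 units. Mitochondrial genes held 8.99% and 6.69% of reads in control microglia, 4.37% and 2.87% at 24 h, 5.58% and 1.7% at 48 h, and 5.19%, 11% and 5.31% in other brain cells. The apolipoprotein gene apoeb took 7.02% of the reads of 48 h sample 8 and 5.21% of those of 48 h sample 4, against 1.83% to 2.59% in the other 4 microglia libraries.

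Comparing control microglia (n = 2) with other brain cells (n = 3) asked which genes differ between microglia and the other cells of the adult brain, whose treatment the labels do not give. The macrophage gene mpeg1.1 (ENSDARG00000055290), whose promoter drives the sorted reporter, stood at 2639 ± 133 (SD, n = 2) in control microglia and 4.16 ± 1.54 (SD, n = 3) in other brain cells. lgals3bpb, a galectin-3-binding protein gene, had the largest difference of the genes ranked, 12630 ± 257 (SD, n = 2) against 17.5 ± 7.84 (SD, n = 3). On the other side, the neuronal genes elavl3, an RNA-binding protein, and snap25a, a synaptic protein, were lower in microglia by -5.49 ± 0.44 and -4.26 ± 0.35 (log2, SE). sox10, a transcription factor of oligodendrocyte development, was at 1.15 ± 0.88 (SD, n = 2) in control microglia against 113.9 ± 16 (SD, n = 3).

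In limma with Benjamini-Hochberg adjustment, 3269 genes were higher and 4379 lower in control microglia among 21714 tested. The 10 largest positive differences ran from 7.97 ± 0.38 for c1qb, a chain of complement C1q (adjusted p = 2.57e-05), to 9.49 ± 0.39 for lgals3bpb (adjusted p = 1.95e-05). Between them lay mpeg1.1 at 9.04 and havcr1 at 8.85. They were followed by the mannose receptor gene mrc1b at 8.75, the chemokine ccl34b.1 at 8.56 and the apolipoprotein apoc1l at 8.52. The others were tgm2l at 8.51, ms4a17a.10 at 8.33 and LGALS3BP (3 of 3) at 8.04. The 10 largest negative differences ran from -5.58 for crp1 and glipr2l to -5.79 ± 0.38 for sox10 (limma, Benjamini-Hochberg adjusted p = 5.35e-05). They included the myelin claudin cldnk at -5.76, sh2d3cb at -5.76, ppp1r14aa at -5.73, and fhl3b at -5.69. The tetraspanin cd9b was at -5.61, the neuroligin nlgn3a at -5.60 and bcan, a matrix proteoglycan of the nervous system, at -5.59. The authors' deposited table has 3894 genes higher and 5409 lower at an FDR under 0.05. Of the genes called here, 3174 and 4124 were among them. Without control sample 1 the counts were 1993 and 1994, and without control sample 5 they were 2041 and 2155. Quantile normalization moved the median of all genes from -0.14 to 0.06, the largest shift among the scalings.

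Among the set genes, the transcription factors spi1b and irf8, which direct macrophage development, were higher in control microglia by 5.58 ± 0.33 and 6.80 ± 0.36 (limma, Benjamini-Hochberg adjusted p = 3.66e-05 and 3.18e-05). The receptor genes csf1ra and p2ry12 were higher by 5.90 ± 0.39 and 3.84 ± 0.41, the transporter slc7a7 by 6.58 ± 0.39 and apoeb by 6.45 ± 0.68. The cytokine genes il1b and tnfa were higher by 5.72 ± 0.37 and 3.61 ± 0.43, with il1b at 268.8 ± 71.7 (SD, n = 2) in control microglia. The myelin gene mbpa was lower by -3.61 ± 0.68 (adjusted p = 0.00357 in limma with Benjamini-Hochberg) yet still stood at 1040 ± 582 (SD, n = 2) in control microglia, and its adjusted p was 0.0817 without control sample 1 and 0.196 without control sample 5. pcna, a replication clamp, mki67, a marker of dividing cells, and the glial filament gene gfap did not pass, at 0.19 ± 0.30, -0.86 ± 0.49 and -0.59 ± 0.35 (limma, Benjamini-Hochberg adjusted p = 0.68, 0.212 and 0.228), and pcna was -0.19 after quantile normalization.

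**Figure D1:**
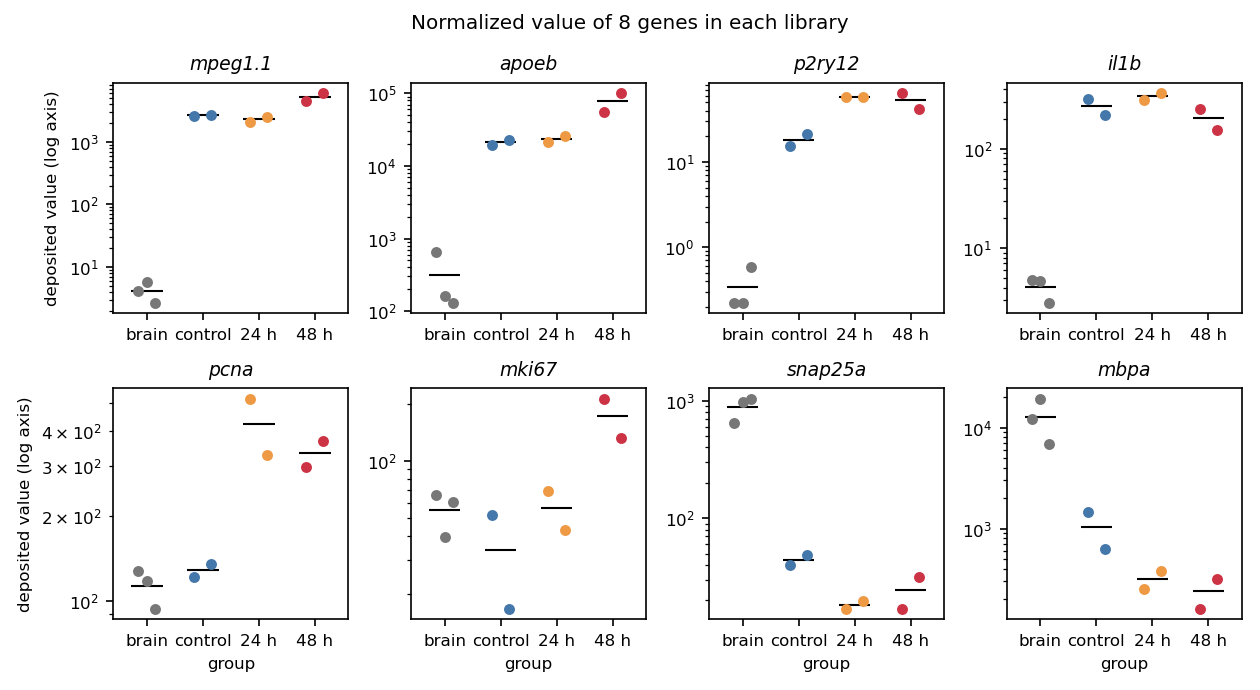
Deposited normalized value (vertical, log axis) of 8 genes in each library of 4 groups (horizontal); each point is 1 library and each bar a group mean. mpeg1.1 lay between 2103 and 6047 in all microglia libraries and at 5.745 or less in other brain cells.

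Genes of microglia identity and immune sensing were higher in control microglia as groups. Of 34 measured microglia core genes, 30 were higher, 0 lower and 4 did not pass, with 32 higher when adjusted over the list alone. For microglia core, the camera adjusted p was 2.75e-24 (adjusted p = 0.0854 with an estimated correlation). Pattern recognition had 24 of 30 higher and 1 lower, 25 and 1 adjusted over the list alone, led by the Toll-like receptor tlr1 at 7.43 ± 0.36, with the scavenger receptor cd36 at -2.57 ± 0.41. For pattern recognition, the camera adjusted p was 8.51e-12 (adjusted p = 0.0854 with an estimated correlation). In antigen presentation, 19 of 23 genes were higher and 0 lower, 22 and 0 adjusted over the list alone, among them cd74a, the class II invariant chain, at 7.77 ± 0.38. For antigen presentation, the camera adjusted p was 3.29e-12 (adjusted p = 0.129 with an estimated correlation). Chemokines and receptors had 39 of 66 higher and 10 lower, 41 and 10 adjusted over the list alone, with ccl19a.1 at 6.51 ± 0.53 and ccl38.6 at -3.73 ± 0.39. For chemokines and receptors, the camera adjusted p was 1.25e-08 (adjusted p = 0.21 with an estimated correlation). Inflammatory mediators had 19 of 36 higher and 2 lower by either adjustment, that is also when adjusted over the list alone. For inflammatory mediators, the camera adjusted p was 3.73e-06 (adjusted p = 0.199 with an estimated correlation). Interferon response had 21 of 33 higher and 1, rsad2, lower, and the same 21 and 1 in number adjusted over the list alone. For interferon response, the camera adjusted p was 1.87e-08 (adjusted p = 0.189 with an estimated correlation). Complement had 5 of 14 higher and 1 lower, 6 and 1 adjusted over the list alone; its median was -0.19, its mean 1.81 and camera pointed up (adjusted p = 0.0393, and adjusted p = 0.331 with an estimated correlation). The complement call was lost without control sample 1 (adjusted p = 0.0783) or other brain cell sample 10 (0.0679), and rsad2 was not called without control sample 1, control sample 5 or other brain cell sample 2 (0.0881, 0.176 and 0.0721).

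Lysosomal, stress and protein synthesis genes were also higher. Lysosome genes were higher in 36 of 61 cases and lower in 5, 40 and 5 adjusted over the list alone, from grna, a progranulin gene, at 7.12 ± 0.35 to atp6ap1a, a proton pump accessory subunit, at -4.21 ± 0.48. For lysosome, the camera adjusted p was 2.57e-10 (adjusted p = 0.128 with an estimated correlation). Damage-associated microglia genes were higher in 16 of 27 cases and lower in 3, 17 and 3 adjusted over the list alone. For damage-associated microglia, the camera adjusted p was 3.39e-07 (adjusted p = 0.128 with an estimated correlation). Immediate early and heat shock genes were higher in 29 of 43 and lower in 0, 31 and 1 adjusted over the list alone, with fosab at 4.39 ± 0.63. For immediate early and heat shock, the camera adjusted p was 8.2e-10 (adjusted p = 0.287 with an estimated correlation). The unfolded protein response had 11 of 29 higher and 0 lower, 15 and 1 adjusted over the list alone. For unfolded protein response, the camera adjusted p was 2.07e-06 (adjusted p = 0.189 with an estimated correlation). For p53 and apoptosis, 14 of 29 were higher and 1, bbc3, lower, also when adjusted over the list alone (camera adjusted p = 5.65e-06, and adjusted p = 0.193 with an estimated correlation), and bbc3 was not called without control sample 1 or any 1 of the other brain cell samples (adjusted p from 0.0551 to 0.161). Cytosolic ribosome genes were higher in 55 of 83 cases and lower in 1, rps8b, 74 and 1 adjusted over the list alone. For cytosolic ribosome, the camera adjusted p was 5.47e-14 (adjusted p = 0.294 with an estimated correlation). Other macrophage and dendritic markers were higher in 14 of 25 and lower in 2, also when adjusted over the list alone, with timd4 at -3.38 ± 0.41. For other macrophage and dendritic markers, the camera adjusted p was 3.16e-07 (adjusted p = 0.119 with an estimated correlation).

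Markers of other brain cells were lower. Neuron markers were lower in 34 of 37 cases and higher in 1, syn2b, 35 and 1 adjusted over the list alone. For neuron markers, the camera adjusted p was 4.57e-14 (adjusted p = 0.189 with an estimated correlation). Radial glia and astrocyte markers were lower in 22 of 27 and higher in 1, the glutamate transporter slc1a3a at 1.85 ± 0.32, with 23 and 1 adjusted over the list alone. For radial glia and astrocyte markers, the camera adjusted p was 2.57e-10 (adjusted p = 0.128 with an estimated correlation). Oligodendrocyte markers were lower in 16 of 19 and higher in 0, 18 and 0 adjusted over the list alone. For oligodendrocyte markers, the camera adjusted p was 2.31e-09 (adjusted p = 0.119 with an estimated correlation). Erythrocyte markers were lower in 11 of 16 and higher in 1, tspo, by either count, also adjusted over the list alone. For erythrocyte markers, the camera adjusted p was 0.00173 (adjusted p = 0.287 with an estimated correlation). Mitosis genes were lower in 17 of 54 and higher in 0, 21 and 0 adjusted over the list alone, with the spindle motor kif11 at -2.92 ± 0.58. For mitosis, the camera adjusted p was 0.00028 (adjusted p = 0.119 with an estimated correlation). Cholesterol synthesis genes were lower in 9 of 28 and higher in 0, 8 and 0 adjusted over the list alone, with hmgcra at -2.31 ± 0.61. For cholesterol synthesis, the camera adjusted p was 0.0187 (adjusted p = 0.287 with an estimated correlation). The cholesterol synthesis call was lost without control sample 1 (adjusted p = 0.0783), and with the control sample 9 column as deposited both cholesterol synthesis (0.162) and mitosis (0.0778) were lost. Single genes not called without control sample 1 were kif11 (adjusted p = 0.0784), syn2b (0.174) and tspo (0.151), and without control sample 5 kif11 (0.0602), syn2b (0.171), tspo (0.128) and hmgcra (0.196). Without other brain cell sample 2, syn2b (0.0893) and tspo (0.0747) were not called, and without sample 10, hmgcra (0.0519). Relative to other brain cells, the median marker stood at 3.89% and 5.36% for neurons, 8.77% and 4.72% for radial glia and astrocytes, 2.63% and 2.53% for oligodendrocytes and 17.8% and 4.67% for erythrocytes in control samples 1 and 5.

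The other 7 lists did not pass in camera. Of DNA replication genes, 0 of 49 were higher or lower, also when adjusted over the list alone (median -0.15, mean -0.09, camera up, adjusted p = 0.801), and with the control sample 9 column as deposited the DNA replication mean was 0.62 and camera called it higher (adjusted p = 0.00962). Glycolysis had 5 of 33 higher and 9 lower, 5 and 10 adjusted over the list alone (camera adjusted p = 0.357), with pfkfb3 at 3.47 ± 0.47 and the neuronal enolase eno2 at -4.03 ± 0.39. Mitochondrial respiration had 1 of 104 higher, COX7A2 (2 of 2), and 6 lower, 0 and 5 adjusted over the list alone (camera adjusted p = 0.479). Without other brain cell sample 10, mitochondrial respiration was called lower (adjusted p = 0.00192), and COX7A2 (2 of 2) was not called without control sample 1 (0.18) or control sample 5 (0.14). Oxidative stress (Nrf2) had 8 of 29 higher and 1 lower, also when adjusted over the list alone, with the heme oxygenase hmox1a at 4.58 ± 0.37 and nqo1 at -3.23 ± 0.54 (camera adjusted p = 0.067). The oxidative stress (Nrf2) list was called without other brain cell sample 2 (adjusted p = 0.039), and nqo1 was not called without control sample 1 (0.0507). Endothelial and mural markers had 3 of 25 higher and 4 lower, also when adjusted over the list alone (median -0.42, mean 0.08, camera up, adjusted p = 0.947), and pecam1 was 6.91 ± 0.42 higher. Neutrophil markers had 5 of 16 higher and 3 lower, also when adjusted over the list alone (median -0.57, mean 0.57, camera up, adjusted p = 0.573), with the Fc receptor chain fcer1gl at 6.24 ± 0.47 and the lysozyme lyz at -4.20 ± 0.80, which was not called without control sample 1 (adjusted p = 0.0746) or control sample 5 (0.0742). Lymphocyte markers had 7 of 26 higher and 7 lower, 7 and 10 adjusted over the list alone (median -0.83, mean -0.03, camera up, adjusted p = 0.94). Of the 20 lists called by camera, 0 held with an estimated correlation (smallest adjusted p = 0.0854) and 20 were also called by fry, which called 22.

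Comparing activated (n = 4) with control microglia (n = 2) asked how microglia change when neurons are lost. Of 49 DNA replication genes 13 rose. Among them mcm2, a subunit of the replicative helicase, stood at 166.3 ± 35.5 (SD, n = 4) in activated and 10.5 ± 4.23 (SD, n = 2) in control microglia, and chaf1a, which assembles chromatin behind the fork, at 62.4 ± 18.3 against 5.35 ± 1.79. Proteasome subunit genes psmd1 and psmd2 rose by 3.58 ± 0.36 and 3.38 ± 0.22 (log2, SE). The median over 46 proteasome subunit genes, a group chosen after the values were seen, was 1.32. The gene hspa5, a chaperone of the endoplasmic reticulum, rose by 2.34 ± 0.31. The chemokine gene ccl19a.1 fell from 736.2 ± 118 (SD, n = 2) to 21.7 ± 9.37 (SD, n = 4), and batf3, a transcription factor of dendritic cells, from 24.2 ± 6.36 to 2.18 ± 1.11. The cytokine gene il1b stood at 271.7 ± 90.3 (SD, n = 4) in activated and 268.8 ± 71.7 (SD, n = 2) in control microglia.

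In limma with Benjamini-Hochberg adjustment, 181 genes rose and 102 fell among 21714 tested, with a smallest adjusted p of 0.0285 and 4456 genes at an unadjusted p under 0.05. These counts rest on leaving out the identical column. As deposited, with the column as a control, limma called 0 and 0 genes (1466 at an unadjusted p under 0.05). With both identical columns left out, the same fit as without 24 h sample 3, it called 0 and 0 (3675). Limma also called 0 and 0 genes without 24 h sample 7 (3631 at an unadjusted p under 0.05) or without 48 h sample 4 (3705). It called 1043 and 507 without 48 h sample 8, 1 and 18 without control sample 1, and 83 and 208 without control sample 5. It also called 0 and 0 with the block for consecutive sample numbers (4374 at an unadjusted p under 0.05) or at an adjusted p under 0.01. The counts were 3 and 1 with the time points as separate groups, 300 and 166 with all 9 libraries, 739 and 379 with array weights, and 477 and 174 with a filter at 5. Limma-voom called 23 and 23. Of the called genes 64.0% rose, against 52.2% with median-of-ratios scaling (129 and 118) and 53.4% with quantile normalization (143 and 125).

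The authors' deposited table held 520 genes that were higher and 720 lower at an FDR under 0.05, and 66 of the risen and 85 of the fallen genes were among them. The risen genes had a median fold change of 1.94 here and 1.42 in the authors' deposited table, and the fallen genes -1.66 and -3.30. Across all genes, which are not independent replicates, Pearson's r between both sets of fold changes was 0.703.

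The 10 largest rises ran from 3.24 ± 0.43 for iars, an isoleucyl-tRNA synthetase (limma, Benjamini-Hochberg adjusted p = 0.044), to 3.92 ± 0.21 for PSMD2 (2 of 2) (adjusted p = 0.0285) and 3.92 ± 0.32 for mms22l, which acts in repair of replication forks (adjusted p = 0.0349). Between them lay mcm2 at 3.89, f13a1b, a coagulation factor XIII gene, at 3.59, psmd1 at 3.58, the splicing factor sf3b4 at 3.43, mcm7 at 3.42, psmd2 at 3.38 and chaf1a at 3.31. Fold changes of these genes were smaller in the authors' deposited table, 2.19 for PSMD2 (2 of 2) with an FDR of 0.113, 3.09 for mms22l with 0.0636, 2.24 for mcm2 with 0.0399 and 1.91 for iars with 0.13. Except for f13a1b, each of the 10 also differed among other brain cell libraries, lowest in sample 6 and highest in sample 10. In samples 2, 6 and 10, psmd2 stood at 15.41, 4.121 and 53.66 and mcm2 at 20.77, 5.961 and 43.72. Over 46 proteasome subunit genes the medians there were 38.1, 35.7 and 35.5. The fit of activated against control microglia left this spread out, and its cause was not tested. The 10 largest falls were -5.15 ± 0.52 for ccl19a.1 (limma, Benjamini-Hochberg adjusted p = 0.0361), -4.09 for siglec15l, -3.30 for the cytokine gene il22, -3.12 for hepacam2 and -3.05 for the potassium channel gene kcnk18. Further falls were -3.03 for batf3, -2.85 for cyth4a, -2.59 for the signaling adaptor hcst, -2.54 for c1qtnf5 and -2.53 ± 0.33 for her15.1 (adjusted p = 0.0429). The authors' deposited table had, in the same order, -5.04 for ccl19a.1 with an FDR of 2.47e-17, -4.22 for siglec15l, -5.04 for il22, -3.13 for hepacam2, -3.84 for kcnk18, -3.54 for batf3, -2.71 for cyth4a, -2.85 for hcst, -5.12 for c1qtnf5 and -4.08 for her15.1. Adding 1 to each value before the log shrinks the folds of genes with low values. It cannot make the rises larger here than in the authors' deposited table. The authors' control group was not control samples 1 and 5 alone, as BX004816.4 below shows, so the folds set unlike control groups side by side. Whether this accounts for the smaller rises was not tested.

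**Figure D2:**
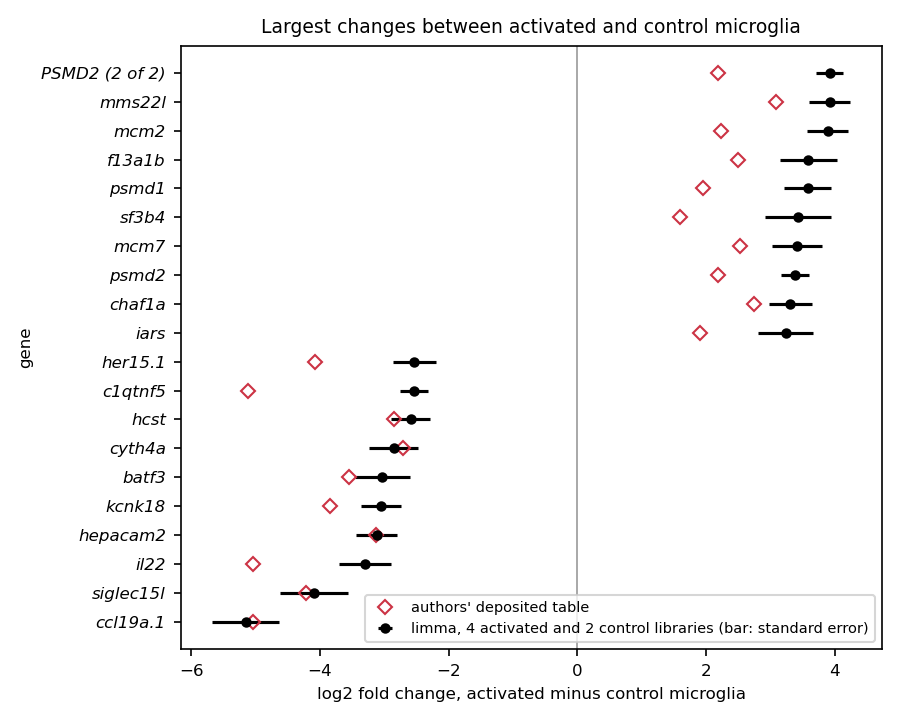
Log2 fold change (horizontal) of the 10 largest rises and 10 largest falls (vertical) between 4 activated and 2 control microglia libraries; black points with bars are limma estimates with their standard error, open diamonds the authors' deposited table. All 10 rises lay farther from 0 in limma than in the authors' deposited table, for example mcm2 at 3.89 against 2.24.

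None of the 15 set genes passed here. p2ry12, a receptor of resting microglia, was at 1.55 ± 0.25 (limma, Benjamini-Hochberg adjusted p = 0.0516), pcna at 1.52 ± 0.27 (adjusted p = 0.0598) and mki67 at 1.67 ± 0.74 (adjusted p = 0.274). apoeb was at 1.00 ± 1.54, mpeg1.1 at 0.38 ± 0.58, csf1ra at 1.02 ± 0.40, slc7a7 at 0.86 ± 0.30, irf8 at -0.52 ± 0.34, spi1b at -0.11 ± 0.25, tnfa at -1.27 ± 0.56 and il1b at -0.03 ± 0.39. Markers of other brain cells were at -1.81 ± 0.77 for gfap, -1.07 ± 0.31 for snap25a, -0.76 ± 0.48 for elavl3 and -1.85 ± 0.47 for mbpa. In the authors' deposited table, mki67 was at 1.87 with an FDR of 0.0063 and pcna at 1.33 with 0.00991.

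Growth and protein handling lists were called higher in activated microglia by camera. DNA replication had 13 of 49 genes risen and 0 fallen, 43 and 0 adjusted over the list alone (median 2.1, camera adjusted p = 3.15e-27, and adjusted p = 0.274 with an estimated correlation). Its median level was 8.41 and 9.2 in control samples 1 and 5, 35 and 32.2 at 24 h and 36.1 and 71.1 at 48 h. Mitosis had 1 of 54 risen, smc2, a condensin subunit, at 2.91 ± 0.38, and 0 fallen, 5 and 0 adjusted over the list alone. For mitosis, the camera adjusted p was 4.56e-12 (adjusted p = 0.365 with an estimated correlation). The unfolded protein response had 2 of 29 risen, hspa5 and the chaperone hsp90b1, and 0 fallen, 14 and 0 adjusted over the list alone. For unfolded protein response, the camera adjusted p was 1.31e-06 (adjusted p = 0.274 with an estimated correlation). Cholesterol synthesis had 2 of 28 risen, hmgcs1 and hmgcrb, and 0 fallen, 4 and 0 adjusted over the list alone. For cholesterol synthesis, the camera adjusted p was 9.17e-05 (adjusted p = 0.274 with an estimated correlation). Lysosome had 1 of 61 risen, the proton pump subunit atp6v1aa at 1.36 ± 0.16, and 0 fallen, also when adjusted over the list alone. For lysosome, the camera adjusted p was 5.67e-05 (adjusted p = 0.365 with an estimated correlation). Mitochondrial respiration had 1 of 104 risen, the ATP synthase subunit atp5b at 1.67 ± 0.24, and 0 fallen, also when adjusted over the list alone. For mitochondrial respiration, the camera adjusted p was 0.000474 (adjusted p = 0.58 with an estimated correlation). The median level of mitochondrial respiration was 36.7 and 40.6 in control samples 1 and 5, 60.7 and 55.8 in 24 h samples 3 and 7, and 35.2 and 112 in 48 h samples 4 and 8, so sample 4 lay below both controls. Oxidative stress (Nrf2) had 2 of 29 risen, prdx1 and keap1b, and 0 fallen, 8 and 1 adjusted over the list alone. For oxidative stress (Nrf2), the camera adjusted p was 0.000753 (adjusted p = 0.344 with an estimated correlation). Glycolysis had 0 of 33 risen or fallen in limma, 9 and 1 adjusted over the list alone. For glycolysis, the camera adjusted p was 0.00138 (adjusted p = 0.287 with an estimated correlation), and the median level was 20 and 36.4 in control, 40.5 and 44.1 at 24 h, and 45.4 and 31 at 48 h. Damage-associated microglia had 0 of 27 risen or fallen, also when adjusted over the list alone (camera adjusted p = 0.0256, and adjusted p = 0.44 with an estimated correlation), and the call of damage-associated microglia was lost without control sample 1 (adjusted p = 0.0896) or 48 h sample 8 (0.145).

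**Figure D3:**
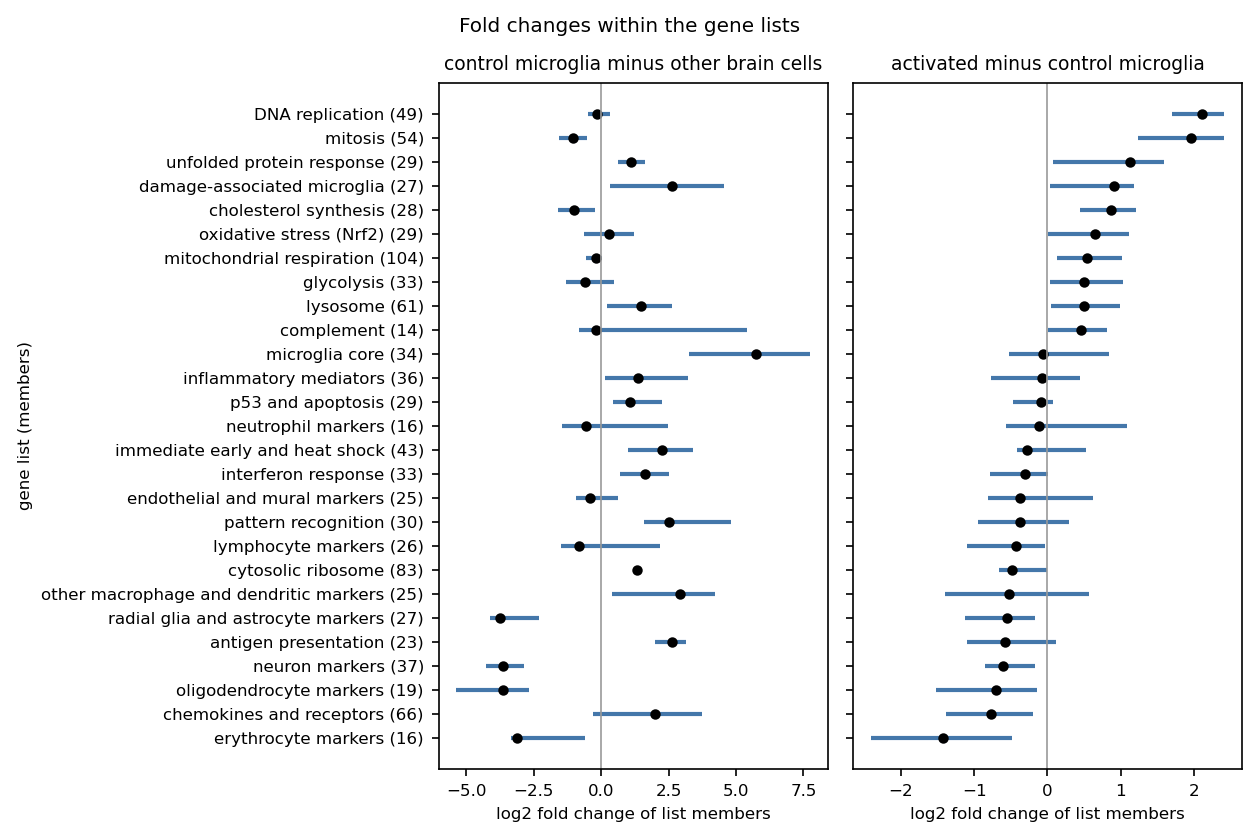
Log2 fold change (horizontal) of the members of 27 gene lists (vertical, member counts in brackets) for both main comparisons; points are medians and lines run from the lower to the upper quartile. In activated minus control microglia, DNA replication had the highest median, 2.1, and erythrocyte markers the lowest, -1.42.

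Camera called chemokine, ribosome, interferon and antigen presentation lists, and markers of several other cells, lower in activated microglia. Chemokines and receptors had 2 of 66 fallen, ccl19a.1 and cxcr3.1, and 0 risen, 8 and 0 adjusted over the list alone. For chemokines and receptors, the camera adjusted p was 1.52e-07 (adjusted p = 0.274 with an estimated correlation). Antigen presentation had 0 of 23 fallen or risen, 2 fallen when adjusted over the list alone (camera adjusted p = 0.00516, and adjusted p = 0.365 with an estimated correlation), with cd74a at 6383 ± 755 (SD, n = 4) against 15240 ± 824 (SD, n = 2). The median level of antigen presentation was 68.5 and 78.2 in control samples 1 and 5, and 59.5, 58.9 and 87.8 in activated samples 3, 7 and 8, with activated sample 4 between the controls, so the groups overlapped. Cytosolic ribosome and interferon response had 0 of 83 and 0 of 33 changed, also when adjusted over the list alone (camera adjusted p = 0.00383 and 0.0297, and adjusted p = 0.68 and 0.44 with an estimated correlation). Both overlapped as well, cytosolic ribosome at 525 and 410 against 426, 317, 217 and 452 (samples 3, 7, 4 and 8), and interferon response at 32.4 and 27.3 against 20.5, 33.3, 28.7 and 26.4. Other macrophage and dendritic markers had 4 of 25 fallen (siglec15l, hepacam2, batf3 and id2a) and 1 risen, f13a1b, 9 and 2 adjusted over the list alone. For other macrophage and dendritic markers, the camera adjusted p was 0.0297 (adjusted p = 0.274 with an estimated correlation). Erythrocyte markers had 2 of 16 fallen, slc4a1a and si:ch211-5k11.6, and 0 risen, 8 and 0 adjusted over the list alone. For erythrocyte markers, the camera adjusted p was 3.24e-06 (adjusted p = 0.274 with an estimated correlation). Radial glia and astrocyte markers had 1 of 27 fallen, the aromatase gene cyp19a1b at -1.63 ± 0.23, and 0 risen, 2 and 0 adjusted over the list alone. For radial glia and astrocyte markers, the camera adjusted p was 0.00108 (adjusted p = 0.274 with an estimated correlation). Neuron and oligodendrocyte markers had 0 of 37 and 0 of 19 changed, 0 and 5 fallen when adjusted over the list alone (camera adjusted p = 0.000981 for both, and adjusted p = 0.274 for both with an estimated correlation). Lymphocyte markers had 0 of 26 changed, also when adjusted over the list alone. For lymphocyte markers, the camera adjusted p was 0.0278 (adjusted p = 0.44 with an estimated correlation). Calls lost without control sample 1 were interferon response (adjusted p = 0.0655), cytosolic ribosome (0.203) and lymphocyte markers (0.376), and without control sample 5 interferon response (0.103) and other macrophage and dendritic markers (0.205). Interferon response was also lost without 24 h sample 3 (0.102) or 48 h sample 4 (0.0525), cytosolic ribosome without 48 h sample 4 (0.08) and lymphocyte markers without 48 h sample 8 (0.125). With the column as deposited, interferon response (0.388) and other macrophage and dendritic markers (0.0882) were lost.

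Levels of these cell markers differed by list and by the members counted. Over all members, the median value of erythrocyte markers was 8.64 and 4.48 in control samples 1 and 5, and 2.08, 2.51, 2 and 3.54 in activated samples 3, 7, 4 and 8. In the same order, neuron markers had medians of 4.7 and 4.79 against 3.09, 3.97, 2.97 and 4.36, radial glia and astrocyte markers 18.8 and 17.7 against 7.59, 11.6, 6.97 and 10.2, and lymphocyte markers 4.63 and 4.03 against 2.28, 3.38, 1.48 and 1.29. Activated libraries and controls overlapped in oligodendrocyte markers, at 5.32 and 2.2 against 2.55, 2.56, 1.37 and 1.35, in endothelial and mural markers, at 1.61 and 2.66 against 1.85, 3.27, 2.4 and 3.35, in neutrophil markers, at 5.71 and 8.9 against 5.57, 15.5, 3.71 and 7.86, and in other macrophage and dendritic markers, at 37.9 and 49.4 against 22.2, 32.6, 24.5 and 40.7. Shares of the level in other brain cells were taken over members whose mean there lay at least 10 above the constant that stands for 0 reads. The median share of erythrocyte markers (12 of 16 members) was 17.8% and 4.67% in control and 0.972%, 1.42%, 0.377% and 0.396% in activated microglia. For oligodendrocyte markers (17 of 19) the shares were 2.63% and 2.53% against 1.08%, 1.72%, 1.09% and 0.572%, for neuron markers (34 of 37) 3.89% and 5.36% against 2.33%, 3.15%, 1.79% and 3.89%, and for radial glia and astrocyte markers (25 of 27) 8.77% and 4.72% against 2.74%, 4.17%, 2.3% and 4.81%. The other 4 lists had 10 or fewer such members, and their shares are not listed here.

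The remaining 8 lists did not pass in camera, and limma called 0 of their genes except fli1a, an endothelial and blood transcription factor. Microglia core had 0 of 34 changed, 3 risen and 3 fallen when adjusted over the list alone (median -0.06, mean 0.00, camera up, adjusted p = 0.947). Complement had 0 of 14 changed, also when adjusted over the list alone (camera adjusted p = 0.128). Inflammatory mediators had 0 of 36 changed, 0 and 3 when adjusted over the list alone (camera adjusted p = 0.155). Pattern recognition and p53 and apoptosis had 0 of 30 and 0 of 29 changed, also when adjusted over the list alone (camera adjusted p = 0.0759 and 0.178). Immediate early and heat shock had 0 of 43 changed, also when adjusted over the list alone (median -0.28, mean 0.01, camera down, adjusted p = 0.743). Neutrophil markers had 0 of 16 changed, also when adjusted over the list alone (median -0.11, mean 0.22, camera down, adjusted p = 0.676). Endothelial and mural markers had 1 of 25 risen, fli1a at 2.07 ± 0.32, and 0 fallen, 3 and 5 adjusted over the list alone (camera adjusted p = 0.178). Of the 19 lists called by camera, 0 held with an estimated correlation (smallest adjusted p = 0.274) and 10 were also called by fry. Calls gained were pattern recognition without 48 h sample 4 (adjusted p = 0.0457), p53 and apoptosis without 48 h sample 8 (0.0279) and immediate early and heat shock without control sample 5 (0.0326).

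**Figure D4:**
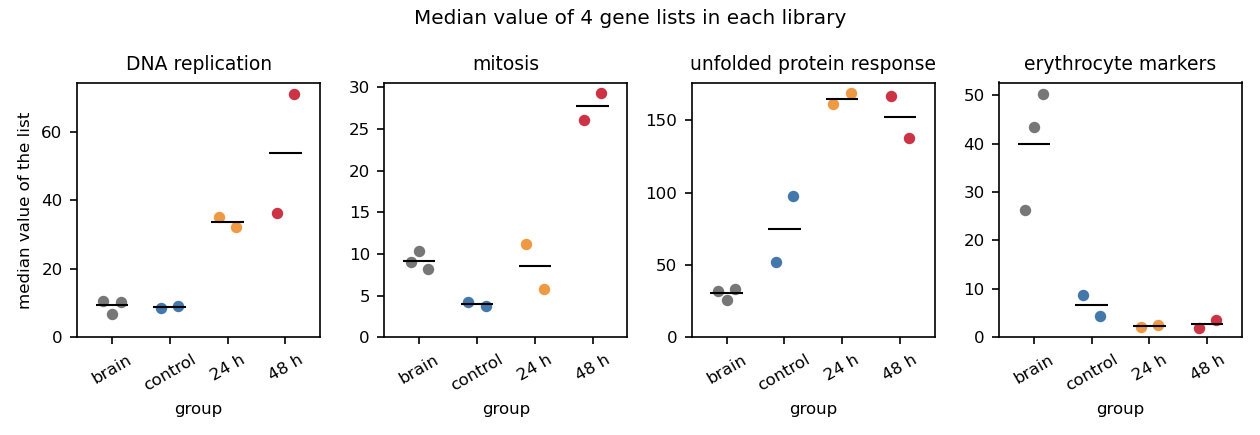
Median normalized value of the members of 4 gene lists (vertical) in each library of 4 groups (horizontal); points are libraries and bars group means. The median mitosis gene stood at 4.24 and 3.72 in control microglia, 11.2 and 5.84 at 24 h and 26.1 and 29.3 at 48 h.

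Comparing activated microglia at 24 h (n = 2) with control microglia (n = 2) asked what had changed by the first time point. BX004816.4 (ENSDARG00000087012), a gene known only by a clone name and chosen after its values were seen, stood at 184.9 and 149 at 24 h, 81.86 and 69.6 at 48 h, 0.996 and 1.29 in control microglia, and 0.331 to 0.861 in other brain cells. DNA replication genes had a median fold change of 1.81, with pcna at 423.2 ± 134 (SD, n = 2) against 128.8 ± 9.37 (SD, n = 2). In limma with Benjamini-Hochberg adjustment, 1 gene, BX004816.4, rose by 6.29 ± 0.25 (adjusted p = 0.0379) and 0 fell, with 3408 genes at an unadjusted p under 0.05. The authors' deposited table gives this gene a fold change of 0.71 with an FDR of 0.892, and has 128 genes higher and 121 lower. That table also has BX004816.4 at 8.28 in control microglia against other brain cells (0.48 in limma), so the control group behind it was not samples 1 and 5 alone. No gene rose by limma without any 1 of the 6 libraries, with the column as deposited (54 genes at an unadjusted p under 0.05), with both identical columns left out (1712) or by limma-voom (0 genes, 3261). The call was also lost with a pseudocount of 5, without the trend, with the block or at an adjusted p under 0.01, while array weights called 3 genes higher and 1 lower.

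Among 4 lists chosen for the time points after the values were seen, camera called DNA replication (adjusted p = 7.18e-24), mitosis and the unfolded protein response (2.13e-07 each) higher and chemokines and receptors (2.13e-07) lower at 24 h. The adjusted p = 0.353 with an estimated correlation held for each of them. Of the 17 lists that camera called at 24 h, fry called 0. Limma called 0 members over all genes, against 34 of 49, 10 of 54, 12 of 29 and 1 of 66 adjusted over the list alone. The set genes did not pass at 24 h, with p2ry12 at 1.62 ± 0.31, csf1ra at 1.26 ± 0.46, irf8 at -0.87 ± 0.30, il1b at 0.36 ± 0.35 and mpeg1.1 at -0.21 ± 0.47 (limma, Benjamini-Hochberg adjusted p = 0.181, 0.299, 0.277, 0.665 and 0.858).

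Comparing activated microglia at 48 h (n = 2) with control microglia (n = 2) asked the same of the second time point. Mitosis genes had a median fold change of 2.72 and DNA replication genes of 2.42, and mki67 stood at 171.5 ± 57.1 (SD, n = 2) against 34.1 ± 24.7 (SD, n = 2). mpeg1.1 stood at 5251 ± 1130 against 2639 ± 133 and apoeb at 78320 ± 32100 against 21070 ± 2150 (SD, n = 2 each). In limma, 0 genes rose and 0 fell (smallest Benjamini-Hochberg adjusted p = 0.0535), with 3966 genes at an unadjusted p under 0.05. Limma-voom also called 0 and 0, all 9 libraries in 1 fit called 190 and 112, a filter at 5 called 81 and 29, robust empirical Bayes 3 and 2 and quantile normalization 2 and 2. The authors' deposited table has 523 genes higher and 386 lower, with mki67 at 2.67 and an FDR of 0.000298.

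For the same 4 lists at 48 h, camera called mitosis (adjusted p = 4.3e-29), DNA replication (4.09e-27) and the unfolded protein response (5.96e-05) higher and chemokines and receptors (4.95e-07) lower, with adjusted p = 0.302 for each of them with an estimated correlation. Of the 20 lists that camera called at 48 h, fry called 3, mitosis (adjusted p = 0.0358) and DNA replication (0.0449) higher and other macrophage and dendritic markers (0.0358) lower. Limma called 0 members over all genes, against 48 of 54, 43 of 49, 12 of 29 and 9 of 66 adjusted over the list alone. None of the set genes passed, with mki67 at 2.46 ± 0.61, gfap at -2.40 ± 0.82 and mpeg1.1 at 0.98 ± 0.47 (limma, Benjamini-Hochberg adjusted p = 0.164, 0.235 and 0.35).

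Comparing 48 h (n = 2) with 24 h (n = 2) tested the difference between the time points itself. Mitosis genes had a median fold change of 1.72, positive in 54 of 54, with mki67 at 171.5 ± 57.1 (SD, n = 2) at 48 h and 56.5 ± 18.7 (SD, n = 2) at 24 h. Microglia core genes had a median of 0.40 and inflammatory mediators of -0.38, with il1b at 204.3 ± 69.9 and 339 ± 37.8. In limma, 0 genes rose and 0 fell (smallest Benjamini-Hochberg adjusted p = 0.892), with 899 genes at an unadjusted p under 0.05 and 0 and 0 called by limma-voom. The authors' deposited table has 6 genes higher and 0 lower at 48 h. Camera called mitosis (adjusted p = 4.29e-38), DNA replication, microglia core (0.00277 each) higher and inflammatory mediators (0.00277) lower, lists chosen after the values were seen, and with an estimated correlation adjusted p = 0.382 for mitosis and inflammatory mediators and 0.823 for the others. Of the 10 lists that camera called for 48 h against 24 h, fry called 0. Adjusted over the list alone, 33 mitosis genes passed and 0 of the other 3 lists. DNA replication had a mean of 0.33, of -0.05 without 48 h sample 8 (adjusted p = 0.507) and of 0.12 without 24 h sample 7 (0.392), and was not called after quantile normalization (0.152). Microglia core was not called without 24 h sample 3 (0.0557) or after quantile normalization (0.293), nor inflammatory mediators without 24 h sample 7 (0.118) or 48 h sample 4 (0.224).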

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

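The tests of explanations and the count of splits in this part were chosen only after the results were seen.

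The column deposited for control microglia sample 9 held, in all 21756 genes, the values of 24 h sample 3. With the column used as 24 h, fold changes lay a median of 0.027 from those in the authors' deposited table, against 0.112 with it left out, which argues against a control library stored under the 24 h label after the authors' fit. A candidate explanation is that the 24 h library was stored under the control label. The deposited 48 h minus control folds lay 0.146 away without the column among the controls and 0.212 away with it, neither as close as 0.027. BX004816.4 stood at 0.996 and 1.29 in control samples 1 and 5 and at 184.9 in the column. Yet the authors' deposited table has it at only 0.71 (log2) for 24 h against control. Their controls thus held the column or another library high in this gene. Folds for control minus other brain cells also lay farther away with the column among the controls, 0.203 against 0.168 without it. This and the 48 h minus control comparison, over 7299 genes, argue against samples 1, 5 and the column as the authors' controls. Which other library they held is unknown. A control library that carried the 24 h label before that fit would correlate most with the controls. The column correlated at 0.974 with 24 h sample 7 and 0.973 with 48 h sample 4, against 0.899 and 0.932 with control samples 1 and 5. These values of 24 h sample 7 and 48 h sample 4 point away from it, though only 2 control libraries were at hand. With 48 h sample 8 the column correlated at 0.913, below control sample 5. The test required every other activated library to lie above both controls, so as a whole it cannot tell. 48 h sample 8 reached at most 0.919 with any library, so its low value is not particular to the column. No biological explanation was tested.

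Higher DNA replication genes in activated microglia were weighed against less RNA of other brain cells. That mixture would raise all microglia genes alike, and the upper quartile of the microglia core folds was 0.84, under the lower quartile of the DNA replication folds, 1.70. A single library as the cause is argued against by the lowest mean of the list with 1 library left out, 1.91 against 2.09 with all. Leaving out 1 library cannot test a trait shared by the only 2 control libraries, so that stays open. The drug itself and the loss of neurons cannot be told apart, because 0 samples received the drug without the transgene. The comparison has 15 splits of the 6 libraries, too few for a share under 0.05 (1 split reached the real 283 genes, and the highest other gave 0).

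Lower genes in activated microglia could come in part from less RNA of neurons, radial glia, oligodendrocytes and erythrocytes, whose highest median share of a marker list in a control was 17.8% (erythrocytes, control sample 1) and highest share of a single marker 383% (slc1a3a). By group means, 79 of the 102 fallen genes dropped by more than 17.8% of their level in other brain cells, and 40 did so by the lowest control minus the highest activated library with both controls at 5 or more. The strictest count, written last, takes 383% in place of 17.8%. Because slc1a3a stood higher in control microglia than in other brain cells, its 383% is no share of carried-over RNA. It serves only as a loose upper bound, and 32 genes lay beyond that explanation even so. The other 70 had a control below 5 or a drop within the bound, and for them that explanation cannot be told apart by this count. RNA of endothelial cells, neutrophils and lymphocytes, whose median marker stood at 41.2% or more of its level in other brain cells in both controls (7 to 10 members a list), is not covered by these counts and stays open. Fewer dendritic-like cells in the activated sorts also cannot be told apart, because the 10 genes of that list, with a median of -2.76, were picked after their values were seen.

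In the 4 activated libraries, a sample stood far from the others by Dixon's ratio in 10 of 92 genes tested, and chance flags about 1 in 20 groups. 48 h sample 8 stood apart in rpa1 (0.899), tnfb (0.892), rps20 (0.891), canx (0.904), hspa8 (0.905), pgd (0.977), tspo (0.853), fcer1gl (0.908), ncf1 (0.904) and its column sum (0.837), and 48 h sample 4 in ccl19a.1 (0.884). Among 15 genes compared between time points, mpeg1.1 lay below both controls in both 24 h libraries and above them in both 48 h libraries, 1.19 ± 0.47 apart on the log2 scale. That difference was singled out by these positions and did not pass in limma (48 h against 24 h, adjusted p = 0.892).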

How the results depend on the processing

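Limma-voom, the column of control microglia sample 9 as deposited and both identical columns left out were alternatives chosen after seeing the data. No paired analysis was possible because the labels pair no samples and the groups share no replicate numbers; a block guessed from consecutive sample numbers was fitted instead. The edgeR and DESeq2 alternatives were not run, and limma-voom on reads recovered from the values was run in their place. Of 210 counts of genes under alternatives, 59 moved by more than 1.5 times. Of 4827 values of named genes, 4398 kept direction and side of the threshold, 43 became called, 326 lost the call and 60 reversed. For lists these numbers were 1248, 16, 97 and 25 of 1386. Genes and lists never called cannot lose a call, so these totals do not measure how stable the calls were. For named genes in activated against control microglia, 141 of 1380 values lost the call under alternatives other than leaving out 1 library, uncalled genes included. Where a group was left with 1 library, that library was assumed to vary like the others. For every change below the cause was not tested. Values below are log2 fold changes, for lists the mean of the members, with the direction taken from the test.

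For control microglia against other brain cells, 2172 genes were higher and 2671 lower at an adjusted p under 0.01, and 1993 to 3243 and 1994 to 4922 leaving out 1 library in turn. For activated against control microglia the counts were 477 and 174 with values of at least 5 in 2 libraries, 739 and 379 with array quality weights, 300 and 166 with all 9 libraries, 3 and 1 with time points as separate groups, 23 and 23 with limma-voom, and 0 and 0 with the block, at an adjusted p under 0.01, with the column as deposited and with both identical columns left out. Leaving out 1 library in turn gave 0 to 1043 and 0 to 507. At 24 h against control, 3 and 1 were called with array weights, and 0 higher with a pseudocount of 5, without the trend, with the block, at an adjusted p under 0.01, with limma-voom, as deposited, with both columns out and leaving out any 1 library (0 to 0). At 48 h against control, 81 and 29 were called with values of at least 5, 2 and 2 with quantile normalization, 3 and 2 with robust empirical Bayes and 190 and 112 with all 9 libraries.

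For control microglia against other brain cells, direction reversed under median-of-ratios scaling (atp5b -0.03, fth1a -0.04), quantile normalization (pcna -0.19, atp5b -0.51, fth1a -0.54, id2a -0.18), block for consecutive sample numbers (fth1a -0.16), control 9 column as deposited (lbr 0.01, id2a -0.15, endothelial and mural markers 0.05, lymphocyte markers -0.18), values of at least 5 in 2 libraries (DNA replication -0.10), fry (DNA replication -0.09, lymphocyte markers -0.03). For activated against control microglia, direction reversed under median-of-ratios scaling (tnfb -0.05, rps20 -0.01), quantile normalization (lgals3bpb 0.63, tnfb -0.12, rps20 -0.06, microglia core -0.10), array quality weights (il1b 0.21, tnfb -0.17, rps20 -0.22, rpl19 -0.07), control 9 column as deposited (lgals3bpb 0.10, stat1b 0.27, neutrophil markers 0.19), both identical columns left out (lgals3bpb 0.09, stat1b 0.17), values of at least 5 in 2 libraries (microglia core 0.00), all 9 libraries in one fit (neutrophil markers 0.22), time points as separate groups (microglia core 0.00), fry (microglia core 0.00). For 24 h against control, direction reversed under median-of-ratios scaling (spi1b -0.08). For 48 h against control, direction reversed under control 9 column as deposited (irf8 0.12). For 48 h against 24 h, direction reversed under quantile normalization (slc7a7 -0.07), both identical columns left out (pcna 0.01, slc7a7 -0.10). Leaving out 1 library in turn, control microglia against other brain cells gave atp5b from -0.25 to 0.44, ccng1 from -0.41 to 0.10, cox7b from -0.91 to 0.02, fth1a from -0.16 to 0.30, lbr from -0.52 to 0.11, DNA replication from -0.20 to 0.02, endothelial and mural markers from -0.04 to 0.17, lymphocyte markers from -0.27 to 0.26, mitochondrial respiration from -0.55 to -0.10. Leaving out 1 library in turn, 48 h against 24 h gave csf1ra from -1.08 to 0.13, elavl3 from -1.07 to 0.21, DNA replication from -0.05 to 0.71, mbpa from -0.94 to 0.03, p2ry12 from -0.44 to 0.15, pcna from -0.64 to 0.01, slc7a7 from -0.10 to 0.47, snap25a from -0.10 to 0.76, tnfa from -0.37 to 1.25. Leaving out 1 library in turn, activated against control microglia gave dusp1 from -0.82 to 0.10, il1b from -0.30 to 0.25, lgals3bpb from -0.23 to 0.15, immediate early and heat shock from -0.33 to 0.34, microglia core from -0.12 to 0.08, neutrophil markers from -0.04 to 0.49, mrc1b from -0.50 to 0.16, rpl19 from -0.16 to 0.36, rps20 from -0.31 to 0.30, slc1a3a from -0.32 to 0.03, spi1b from -0.30 to 0.09, stat1b from -0.60 to 0.17, tnfb from -0.48 to 0.62, zgc:56493 from -0.02 to 0.74. Leaving out 1 library in turn, 48 h against control gave irf8 from -0.49 to 0.15. Leaving out 1 library in turn, 24 h against control gave spi1b from -0.15 to 0.24.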

Other observations

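The 6 gene groups here and their tests were chosen only after the values were seen, so their p-values are not independent evidence. In activated against control microglia, 5 of 46 proteasome subunit genes rose and 0 fell, with psmd3 at 3.17 ± 0.43 and psmd6 at 1.13 ± 0.17 (limma camera, Benjamini-Hochberg adjusted p = 6.44e-16, and adjusted p = 0.107 with an estimated correlation). Nucleoporin genes, which build the nuclear pore, rose in 6 of 28 cases, with nup50 at 2.35 ± 0.29 and nup188 at 2.30 ± 0.29 (camera adjusted p = 1.38e-15, and adjusted p = 0.00473 with an estimated correlation). Chaperonin subunits, which fold actin and tubulin, rose in 4 of 9 cases, with tcp1 at 2.13 ± 0.21 and cct4 at 1.94 ± 0.17 (camera adjusted p = 3.68e-10, and adjusted p = 0.0435 with an estimated correlation). Aminoacyl-tRNA synthetases rose in 2 of 22 cases, iars and larsb (camera adjusted p = 2.77e-14, and adjusted p = 0.0936 with an estimated correlation), and coatomer genes of vesicle transport in 2 of 9, copb2 and copg2 (camera adjusted p = 0.000139, and adjusted p = 0.094 with an estimated correlation). In the authors' deposited table, 16 proteasome, 4 nucleoporin, 0 chaperonin, 4 synthetase and 1 coatomer genes were higher at an FDR under 0.05.

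Dendritic-like markers fell in 5 of 10 cases (ccl19a.1, siglec15l, hepacam2, batf3 and id2a), with 10 of 10 below 0 (camera adjusted p = 7.73e-11, and adjusted p = 0.0411 with an estimated correlation). Of the others, flt3, a growth factor receptor of dendritic cell precursors, was at -2.50 ± 0.71 and il12ba, a cytokine subunit gene, at -3.23 ± 0.66 (limma, Benjamini-Hochberg adjusted p = 0.129 and 0.0743). In the authors' deposited table, 9 of the 10 were lower. These calls rest on the same 2 control libraries as the rest of the comparison.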
